A study of Saccharomyces cerevisiae and Saccharomyces pastorianus with 78 samples.

How the data were processed

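Poly(A) RNA of 78 yeast samples was sequenced, 39 from *Saccharomyces cerevisiae* BY4741 and 39 from the lager yeast *S. pastorianus* Weihenstephan 34/70. Cultures grown in YPD at 25 °C to an OD595 of about 0.1 were treated with 0.01% SDS or 7% EtOH and sampled 0.5, 1, 2, 4 and 8 h and 20 h later. Controls were taken just before the addition, and each of the 13 groups per yeast had 3 biological replicates. Each culture was split into 2 aliquots, and the control came from the aliquot that then received EtOH. The SDS aliquot had no control of its own, and no untreated culture was sampled at the later times. Time after addition and time in culture are therefore not separated, and both stresses were compared with the same controls.

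Per the labels, the authors ran FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.8 and featureCounts 2.0.1, with build R64 for *S. cerevisiae*. The authors deposited 1 table of raw counts per gene for each yeast, with whole numbers and no normalization. The deposited annotation of *S. pastorianus* gives feature start and end positions on scaffolds, as stored by the authors, and pairs no identifier with a gene name or a parental subgenome. Strandedness and the handling of multimapped reads are not given in the sources used here. The BY4741 libraries held 3105804 to 21167236 counts (median 7706767) and the *S. pastorianus* libraries 23992590 to 47297347 (median 30852083). A gene with a count of 0 in a library is allowed up to 3 counts, which is 0.966 CPM (counts scaled to library size) in the smallest BY4741 library and 0.142 CPM in the largest. This floor covers counting error only, since the reads carry no molecular identifiers.

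Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately for each yeast. Genes were kept by filterByExpr on the 13 groups, which left 6101 of 7127 BY4741 features and 10688 of 11956 *S. pastorianus* features. Libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 39 libraries, with 26 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its absolute log2 fold change was at least 1. Each time of each stress was compared with the control. F tests over the 6 times gave the genes that changed at any time, with the same limits applied to the largest of the 6 changes. A further F test compared EtOH with SDS at matched times. Log2 changes are given with an approximate standard error (SE), derived as the absolute log2 change over the square root of its F statistic. Levels are CPM given as mean ± standard deviation (SD) of n = 3 libraries. Replicate numbers were not used as pairs in these fits.

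For BY4741, 28 gene lists were written before the data were examined. They cover heat shock chaperones, general stress response, trehalose and glycogen, cell wall integrity, multidrug resistance, ergosterol, sphingolipids, eisosomes, fatty acids and phospholipids, ribosomal proteins, ribosome biogenesis, proteasome, unfolded protein response and respiratory chain. They also cover the tricarboxylic acid (TCA) and glyoxylate cycles with gluconeogenesis, glycolysis, hexose transporters, glycerol and osmotic response, oxidative stress, iron, amino acids, phosphate, cell cycle, histones, ESCRT, autophagy, and 2 cell-type lists (haploid mating genes, meiosis and sporulation). Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjusted p over the 168 tests of a stress (28 lists at 6 times). A list was called at an adjusted p under 0.05. Camera with a correlation estimated from the data and fry were run beside it. Camera compares the members of a list with the other genes, while fry asks only whether the members changed. Counts "adjusted over the list alone" use Benjamini-Hochberg over the members of that list.

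Named genes followed a rule fixed before the data were examined. At each time, the 3 largest rises and 3 largest falls were taken among called genes with a mean of at least 20 CPM whose 3 treated libraries all lay on 1 side of the 3 controls. Between the stresses, the 5 largest mean differences in each direction with 1 sign at all 6 times were taken. Of these, 1 gene is not reported. In each list, up to 4 members with the largest change were taken at the time with most called members. A set of 12 genes was followed in every course, and HIS3, LEU2, MET17 and URA3 were read as strain markers. The 4 *S. pastorianus* identifiers printed in the report, the haploid-specific and alpha-specific genes and SST2 of the closing section and the gene families grouped by symbol fall outside this rule and were chosen after their values were seen.

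Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, fits of only the 6 compared libraries, and leaving out each library. Chosen after seeing the data were F tests without 20 h, list tests without 1 replicate, and *S. pastorianus* libraries thinned to the BY4741 totals. The pipeline was tested on simulated data made from the fitted means, library sizes and dispersions of the real libraries, with 200 genes changed in each yeast. Planned tests of orthologues between the yeasts, of pairs of parental gene copies and of gene lists in *S. pastorianus* were not run, since they need gene names or subgenomes. *S. pastorianus* results are therefore given as counts of genes and as identifiers.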

Results

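RNA was sequenced from *S. cerevisiae* BY4741, a haploid laboratory strain, and from *S. pastorianus* Weihenstephan 34/70, a lager brewing hybrid. Each yeast was sampled before the addition of 0.01% SDS, an anionic detergent, or 7% EtOH, and at 6 times from 0.5 to 20 h after it. Every group held 3 biological replicates, which gave 39 libraries per yeast. BY4741 libraries totalled 3105804 to 21167236 counts and *S. pastorianus* libraries 23992590 to 47297347. LEU2, MET17 and URA3, which the BY4741 background lacks, had 0 counts in all 39 BY4741 libraries, which allows up to 0.966 CPM in the smallest of them. HIS3, a histidine synthesis gene partly deleted in this background, had 310 to 2650 counts per library.

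SDS in BY4741. The first comparison asked which genes responded to SDS over time. HSP12 (YFL014W, build R64, chromosome VI, 107256 to 107585), which encodes a membrane-associated stress protein, rose from 1.98 ± 0.96 CPM in the control to 509 ± 98.4 CPM at 0.5 h and 1750 ± 788 CPM at 4 h (SD, n = 3). Its log2 change was 8.00 ± 0.56 (SE) at 0.5 h, 9.78 ± 0.59 at 4 h and 3.32 ± 0.59 at 20 h. RTA1 (YGR213C, chromosome VII, 918512 to 919465), a membrane protein gene of the lipid-translocating exporter family, rose from 21.2 ± 0.277 to 391 ± 9.83 CPM at 0.5 h. NOP7 (YGR103W, chromosome VII, 695417 to 697234), needed to make the large ribosomal subunit, fell from 720 ± 44.0 to 89.8 ± 19.9 CPM at 0.5 h. STE2 (YFL026W, chromosome VI, 82580 to 83875), the receptor for alpha-factor, fell from 644 ± 36.2 to 183 ± 2.54 CPM at 2 h.

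At 0.5 h, 518 genes rose and 645 fell of 6101 tested in edgeR, 1163 in all. At 1, 2, 4, 8 and 20 h, 692, 578, 639, 375 and 285 genes were called, of which 353, 354, 469, 251 and 165 rose. Over all times 1528 genes (25.0%) changed, and 864 of them changed most at 0.5 h.

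Among the largest rises other than HSP12 were those of CPP3 at 0.5 to 4 h, PDH1, a propionate metabolism gene, at 1 h, and NQM1, a transaldolase paralog, at 2 and 4 h. CPP3 rose from 1.36 ± 0.0395 to 89.7 ± 12.7 CPM at 4 h, and NQM1 from 6.96 ± 1.34 to 443 ± 114 CPM. The acid phosphatase gene PHO5 (YBR093C, chromosome II, 429548 to 430951) rose from 76.3 ± 9.16 to 1240 ± 105 CPM at 20 h. TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, rose by a log2 change of 3.70 ± 0.49 at 20 h, and the phosphate transporter gene PHO89 by 3.08 ± 0.22. Among the largest falls at 0.5 h were those of PRM10 (-3.69 ± 0.26), CHA1 (-3.45 ± 0.36), a serine and threonine deaminase gene, and PHO3 (-3.08 ± 0.24), an acid phosphatase gene. Among the larger falls at 1 h were those of the cell wall mannoprotein gene TIP1 (-2.89 ± 0.23) and of ZEO1 (-2.86 ± 0.16). GSY1, a glycogen synthase gene, fell by 2.73, 3.22 and 3.39 at 2, 4 and 8 h, and the maltose permease gene MAL31 and the hexose transporter gene HXT4 fell by 2.69 and 2.62 at 2 h. NDJ1, a meiotic telomere gene, fell by 2.77 at 4 h. NCE103, the carbonic anhydrase gene, fell by 3.14 ± 0.46 at 20 h from a control level of 374 ± 233 CPM, and its change was -2.5 without control replicate 1.

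**Figure D1:**
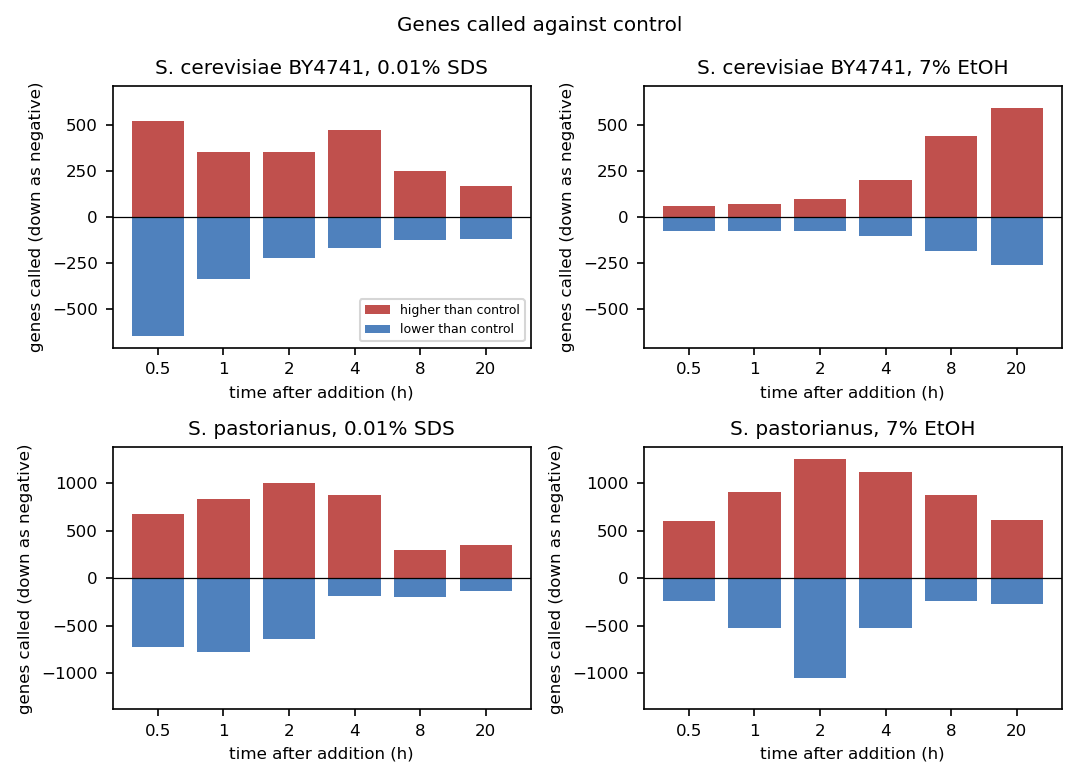
Genes called against the control (y axis, number of genes, falls drawn as negative) by time after addition in hours (x axis), for each yeast and stress. Bars above 0 are rises and bars below 0 are falls: in BY4741 the SDS count was highest at 0.5 h with 1163 genes, and the EtOH count at 20 h with 849.

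Stress and protein-quality genes. The general stress response list rose at all 6 times, with 14, 10, 13, 17, 8 and 8 of 19 measured members up and 1 down at 8 h. Its median log2 change was 1.53, 1.30, 1.34, 2.23, 0.72 and 0.80, and the adjusted p ran from 2.62e-12 at 4 h to 0.000274 at 20 h. At 4 h the call held (adjusted p = 0.0448 with an estimated correlation), and at the other times this adjusted p lay between 0.106 and 0.352 with an estimated correlation. At 4 h DDR2 rose by 4.13 ± 0.30, CTT1, the cytosolic catalase gene, by 3.06 ± 0.23, and MSC1 by 2.94 ± 0.25. Adjusted over the list alone, the counts of called members equalled those over all genes in each SDS list, except for the heat shock chaperones at 4 h (4 down in place of 5) and the ribosomal proteins at 4 h (1 up in place of 0) and 8 h (0 up in place of 1). The heat shock chaperones fell at 2 h, with 6 of 22 members down and 2 up, a median of -0.54 and an adjusted p of 0.0368 (adjusted p = 0.838 with an estimated correlation). Without replicate 1 that adjusted p was 0.125. SSA2, an Hsp70 gene, fell by 1.37 ± 0.22 and CUR1, a protein-sorting factor gene, by 2.02 ± 0.52. Of the 50-base sequences of SSA2, 58.15% occur more than once in the genome. The members that rose at 2 h were HSP26, a small heat shock protein gene, by 1.92 ± 0.68 and the Hsp70 gene SSA4 by 1.46 ± 0.55, and both calls were lost when single libraries were left out, with adjusted p up to 0.0579 and 0.0863. HSP26 also rose by 3.12 ± 0.66 at 0.5 h, 2.57 ± 0.67 at 1 h, 3.95 ± 0.67 at 4 h and 3.25 ± 0.66 at 8 h, from 7.97 ± 0.637 CPM to 123 ± 16.5 CPM at 4 h, and at 20 h its change of 1.49 ± 0.69 (adjusted p 0.0943) was not called, except by DESeq2 (0.0358) and when only the 6 compared libraries were fitted (0.000312). SSA4 rose by 1.91 ± 0.56 at 4 h. HSP104, KAR2 and RPN4 were not called at any SDS time, with changes of -0.58 to 0.74, -0.82 to 0.19 and -0.44 to 0.20. The chaperones were not called at the other times, with medians of 0.16, -0.64, -0.26, -0.27 and -0.28 and adjusted p from 0.134 to 0.864.

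The proteasome list rose at 0.5 and 1 h (medians 0.84 and 0.37, 4 and 0 of 32 members up, adjusted p 4.65e-13 and 9.8e-07). It fell at 4 and 8 h (medians -0.32 and -0.28, no member called, adjusted p 1.71e-05 and 2.51e-07), and the adjusted p was 0.174, 0.376, 0.434 and 0.364 at these 4 times with an estimated correlation. RPT2, a gene for an ATPase of the regulatory particle, rose by 1.16 ± 0.09 at 0.5 h. The unfolded protein response list rose at 0.5 h with a median of 0.40 and 0 of 14 members called (adjusted p 0.0467, and adjusted p = 0.545 with an estimated correlation). Without replicate 2 its adjusted p was 0.0708. Autophagy genes rose at 0.5 h (4 of 15 up, median 0.78, adjusted p 0.0012) and 4 h (3 up, median 0.27, adjusted p 0.0488), with adjusted p = 0.336 and 0.559 with an estimated correlation. At 4 h the adjusted p was 0.0657 without replicate 2. ATG8, whose product coats the autophagosome, rose by 2.14 ± 0.23 at 0.5 h, and ATG34 by 2.48 ± 0.16. The ESCRT list rose at 0.5 h with a median of 0.35 and 0 of 14 members called (adjusted p 0.0259, and adjusted p = 0.404 with an estimated correlation).

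Growth genes. Of 26 ribosome biogenesis genes, 25 fell at 0.5 h, 8 at 1 h and 1 at 2 h. The median was -1.85, -0.82 and -0.40, and -0.41 at 20 h with no member called. The adjusted p was 2.28e-14, 5.84e-08, 0.000835 and 0.000384 at these 4 times, against 0.219, 0.395, 0.66 and 0.635 for the adjusted p with an estimated correlation. NUG1, needed for export of the large subunit, fell by 2.55 ± 0.19, and RPA135, a gene for an RNA polymerase I subunit, by 2.28 ± 0.19. Of 19 single-copy ribosomal protein genes, 17, 14, 9 and 4 fell at 0.5, 1, 2 and 4 h, with medians of -1.44, -1.16, -1.0 and -0.86 and adjusted p from 4e-07 to 6.4e-05. The adjusted p was 0.364 to 0.472 with an estimated correlation. RPP0, the stalk protein gene, fell from 2900 ± 182 to 871 ± 45.5 CPM at 0.5 h. Cell cycle genes fell at 0.5 h (8 of 13 down, median -1.12, adjusted p 1.27e-05), 2 h (2 down, -0.50, 0.00967) and 20 h (0 down, -0.36, 0.00622), with adjusted p = 0.148, 0.404 and 0.376 with an estimated correlation. RNR1, a ribonucleotide reductase gene, fell by 1.73 ± 0.15. Histone genes fell at 0.5 h (5 of 8 down, median -1.03) and 1 h (4 down, -0.99) and rose at 8 and 20 h (medians 0.57 and 0.71, no member called), with adjusted p from 9.65e-05 to 0.00358 and from 0.364 to 0.472 with an estimated correlation. PMA1, the plasma membrane proton pump gene, fell by 1.76 ± 0.17 at 0.5 h and had a log2 change of -0.07 ± 0.17 at 8 h.

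Membrane, wall and transport genes. The multidrug resistance list rose at all 6 times, with 7, 6, 4, 5, 3 and 7 of 13 members up and 1 down up to 4 h. Its medians were 1.08, 0.67, 0.80, 0.79, 0.53 and 1.04, with adjusted p from 6.39e-06 at 20 h to 0.0105 at 1 h. The call held at 20 h (adjusted p = 0.0431 with an estimated correlation), and the estimate gave an adjusted p of 0.0834 to 0.263 at earlier times. TPO1, a polyamine exporter gene, rose by 2.39 ± 0.19 at 0.5 h, and PDR10 and PDR15, which encode ABC transporters, by 2.25 ± 0.10 and 2.13 ± 0.28. PDR5, the main ABC multidrug pump gene, had changes of 0.27 to 0.63 with adjusted p of 3e-05 to 0.039. It was not called because the log2 changes lay under 1. PDR12, a weak-acid exporter gene, fell by 1.07 to 1.26 from 0.5 to 4 h. Cell wall integrity genes rose from 1 to 20 h, with 4, 7, 8, 7 and 6 of 20 members up, 1 down at 1, 2 and 20 h, and medians of 0.32, 0.73, 0.90, 0.86 and 0.54. The adjusted p ran from 1.69e-08 to 0.025. The call held at 8 h (adjusted p = 0.0448 with an estimated correlation), and the estimate gave an adjusted p of 0.421, 0.148, 0.0653 and 0.174 at 1, 2, 4 and 20 h. At 0.5 h the list was not called (5 up, 1 down, median 0.38, adjusted p 0.118). GSC2 (YGR032W, chromosome VII, 548264 to 553951), a beta-glucan synthase gene, rose from 136 ± 15.6 to 918 ± 55.9 CPM at 2 h. CRH1, a chitin transglycosylase gene, rose by 2.03 ± 0.17 and YPS3, an aspartic protease gene, by 2.11 ± 0.14. SLT2, the kinase gene of the cell wall integrity pathway, had changes of 0.12 to 0.64 and was not called. Its adjusted p was 0.48 at 1 h and 0.00017 to 0.024 at the other times.

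The eisosome list rose at 20 h with a median of 0.28 and 0 of 10 members called (adjusted p 0.0314, and adjusted p = 0.406 with an estimated correlation). SUR7 fell by 1.38 ± 0.12 at 0.5 h. The fatty acid and phospholipid list rose at 20 h (2 of 14 up, median 0.39, adjusted p 0.0334, and adjusted p = 0.278 with an estimated correlation), and its adjusted p was 0.0597 without replicate 2. INO1 (YJL153C, chromosome X, 134332 to 135933), the inositol phosphate synthase gene, rose from 17.3 ± 4.18 to 274 ± 27.8 CPM at 0.5 h and 456 ± 58.7 CPM at 4 h. OPI3, a phospholipid methyltransferase gene, rose by 2.98 ± 0.24 at 0.5 h, and the fatty acid activation gene FAA4 fell by 2.19 ± 0.16. OLE1, the fatty acid desaturase gene, fell by 1.27 ± 0.28 at 0.5 h. The ergosterol list was not called at any time (medians -0.07 to 0.32, adjusted p 0.0516 to 0.891), but it was at 1 h without replicate 1 or 3 (0.0388 and 0.024), at 2 h without replicate 3 (0.0113) and at both times by fry (0.0128 and 0.0296). ERG11 was not called, with a change of -0.61 ± 0.09 at 0.5 h (adjusted p 6.3e-07) and of 0.19 ± 0.09 at 20 h (0.1). At 0.5 h ERG9, the squalene synthase gene, rose by 1.09 ± 0.10 and ERG3, a sterol desaturase gene, fell by 1.19 ± 0.14. The sphingolipid list was not called (medians -0.09 to 0.12, adjusted p 0.0721 to 0.934), and at 0.5 h ELO3, a fatty acid elongase gene, fell by 1.67 ± 0.13 and the kinase gene YPK1 rose by 1.31 ± 0.08.

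Metabolic genes. The respiratory chain list rose at all 6 times, with 5, 4, 2, 1, 0 and 3 of 25 members up and medians of 0.69, 0.71, 0.65, 0.55, 0.36 and 0.75. Its adjusted p ran from 2.28e-14 to 1.35e-05, and the call held except at 8 h (adjusted p = 0.0525 with an estimated correlation). CYT1, the cytochrome c1 gene, rose by 1.38 ± 0.11 at 0.5 h. The TCA, glyoxylate and gluconeogenesis list rose at all 6 times (10, 8, 6, 7, 4 and 4 of 21 up, medians 1.00, 0.86, 0.62, 0.50, 0.25 and 0.35). Its adjusted p ran from 4.32e-06 to 0.00358. The call held at 1 and 2 h (adjusted p = 0.0355 and 0.0431 with an estimated correlation), and the estimate gave 0.0525, 0.0525, 0.15 and 0.144 as adjusted p at 0.5, 4, 8 and 20 h. CIT1, the citrate synthase gene, rose by 1.89 ± 0.13 and ACO1, the aconitase gene, by 1.72 ± 0.16 at 0.5 h. Glycerol and osmotic genes rose except at 8 h (6, 6, 4, 4, 2 and 2 of 10 up, medians 1.41, 1.14, 1.00, 0.66, 0.27 and 0.39), with adjusted p from 0.00097 to 0.00967 when called, and from 0.118 to 0.229 with an estimated correlation. GRE2 (YOL151W, chromosome XV, 43694 to 44722), a methylglyoxal reductase gene, rose from 112 ± 1.14 to 1960 ± 97.2 CPM at 0.5 h, and GPP2, a glycerol phosphatase gene, by 2.80 ± 0.23. Trehalose and glycogen genes rose at 0.5 h (6 of 16 up, 2 down, median 0.81, adjusted p 0.0164) and fell at 8 h (5 down, -0.59, 1.22e-05), with adjusted p = 0.613 and 0.312 with an estimated correlation. GDB1, the glycogen debranching gene, rose by 1.71 ± 0.19 at 0.5 h. The glycolysis list fell at 4 h (1 up and 1 down of 14, median -0.33, adjusted p 0.0368, and adjusted p = 0.622 with an estimated correlation), with adjusted p of 0.105 and 0.0799 without replicate 1 or 3. ENO1, an enolase gene, rose by 2.29 ± 0.37 and the hexokinase gene HXK2 fell by 1.27 ± 0.10. Of the 50-base sequences of ENO1, 23.64% occur more than once in the genome. Hexose transporters were not called as a list (3, 4, 4, 4, 4 and 1 of 7 members down, 1, 0, 1, 1, 1 and 0 up, medians -1.69 to -0.22, adjusted p 0.069 to 0.986). Without replicate 3 they were called at 0.5, 1 and 8 h (0.0434, 0.0422 and 0.0176), and by fry from 0.5 to 2 h and at 8 h (2.53e-06 to 0.00829). HXT2 fell by 1.16 ± 0.22 at 2 h. The oxidative stress list was not called (medians -0.17 to 0.18, adjusted p 0.0727 to 0.932), and the thioredoxin gene TRX2 rose by 1.17 ± 0.11 at 0.5 h. Amino acid genes rose at 20 h (3 of 17 up, median 0.18, adjusted p 0.0484, and adjusted p = 0.46 with an estimated correlation), with adjusted p of 0.0657 and 0.0553 without replicate 1 or 2.

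Iron uptake genes fell at all 6 times, with 7, 9, 9, 8, 7 and 12 of 17 members down, 1 up at 4 h, and medians of -0.86, -1.02, -1.04, -0.84, -0.93 and -1.52. The adjusted p ran from 1.83e-11 at 20 h to 0.00135, against 0.0797 at 20 h and 0.352 to 0.421 earlier for the adjusted p with an estimated correlation. FIT1 (YDR534C, chromosome IV, 1503314 to 1504900), a siderophore-binding wall mannoprotein gene, fell from 275 ± 49.2 to 18 ± 6.82 CPM at 20 h, and FET3, the iron oxidase gene, by 2.13 ± 0.18. Phosphate uptake and storage genes rose from 1 to 20 h, with 6 of 10 members up at each of these times and medians of 1.21, 1.59, 1.87, 1.6 and 1.5. The adjusted p ran from 2.04e-09 to 4.51e-05. The call held at 8 and 20 h (adjusted p = 0.0486 and 0.0458 with an estimated correlation), and the estimate gave an adjusted p of 0.181, 0.118 and 0.0834 at 1, 2 and 4 h. PHO84, the high-affinity phosphate transporter gene, rose by 1.31 ± 0.20 at 1 h. The haploid mating genes fell at all 6 times, with 7, 7, 8, 8, 8 and 7 of 9 down, 1 up from 1 h, and medians of -1.18, -1.06, -1.80, -2.27, -1.78 and -1.72. The adjusted p ran from 1.83e-11 to 0.000183, and the call held from 1 h on (adjusted p = 0.00226 to 0.0431 with an estimated correlation) but not at 0.5 h (0.0653). The a-factor gene MFA2 fell from 141 ± 4.95 to 21.7 ± 4.43 CPM at 4 h, and FUS1, which acts in cell fusion, fell by 3.13 ± 0.24 at 8 h. The meiosis and sporulation list was not called (medians 0.17 to 0.58, adjusted p 0.125 to 0.796), and IME2, a meiotic kinase gene, fell by 1.66 ± 0.22 at 0.5 h. Other SDS list tests that gained a call without 1 replicate were those of the heat shock chaperones (0.0396), cell cycle (0.0358) and autophagy genes (0.0309) at 1 h, autophagy at 2 h (0.0218), the fatty acid list at 8 h (0.0157) and sphingolipids at 20 h (0.0388). In the SDS course, the median, mean and test differed in sign in 17 list tests, and none of these was called.

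**Figure D2:**
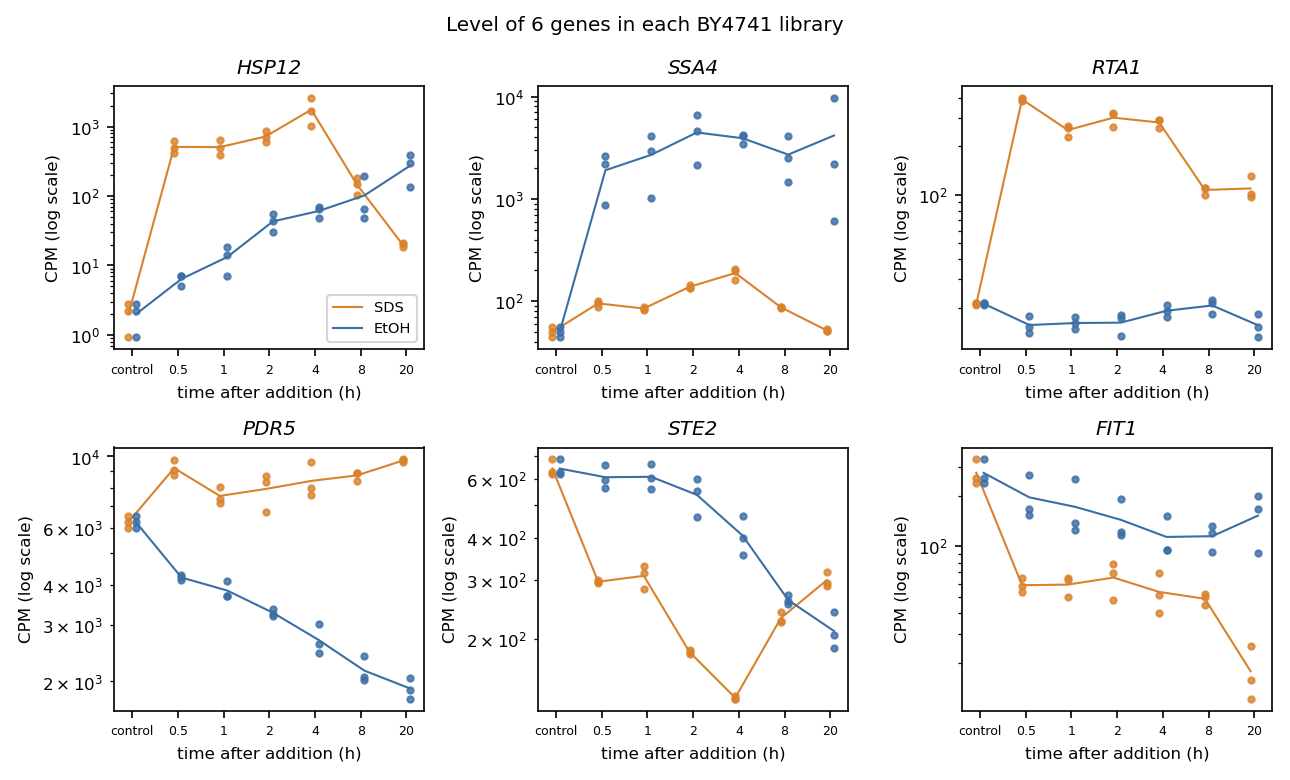
Level of 6 BY4741 genes in CPM (y axis, log scale) by time after addition in hours (x axis), with 1 point per library and lines through the means of 3 replicates, for SDS and EtOH. HSP12 reached a mean of 1750 CPM at 4 h of SDS and 273 CPM at 20 h of EtOH, and SSA4 in EtOH spread from 608 to 9690 CPM at 20 h.

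EtOH in BY4741. This comparison asked the same of EtOH. SSA4 (YER103W, chromosome V, 364589 to 366517), a stress-inducible Hsp70 gene, rose from 50.0 ± 5.63 CPM to 1900 ± 920 CPM at 0.5 h and 4460 ± 2230 CPM at 2 h (SD, n = 3), log2 changes of 5.25 ± 0.63 and 6.48 ± 0.67. HSP26 (YBR072W, chromosome II, 382030 to 382674), a small heat shock protein gene, rose from 7.97 ± 0.637 to 1010 ± 527 CPM at 2 h. TDH1 (YJL052W, chromosome X, 338271 to 339269) rose from 75.4 ± 18.4 to 6630 ± 784 CPM at 8 h. PDR5 (YOR153W, chromosome XV, 619840 to 624375) fell from 6260 ± 276 to 1900 ± 144 CPM at 20 h. HXT2 (YMR011W, chromosome XIII, 288079 to 289704), a glucose transporter gene, fell from 2130 ± 185 to 550 ± 42.8 CPM at 0.5 h.

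The number of called genes was 133, 143, 173, 306, 623 and 849 from 0.5 h to 20 h in turn, of which 56, 67, 95, 201, 439 and 590 rose. Over all times 1107 genes (18.1%) changed, and 655 of them changed most at 20 h. Replicates 1 and 3 stood apart at 20 h, where SSA4 lay at 608, 2180 and 9690 CPM in replicates 1, 2 and 3. The mean SD of log2 CPM between replicates was 0.319 at this time, against 0.132 to 0.209 in the other BY4741 groups. The SE printed for 20 h come from the fit of all 13 groups and do not measure the spread of this group alone. The 20 h count was 689 without replicate 3 and 1053 without replicate 1, and the count over all times was 714 without the 20 h comparison.

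HSP12 rose by 2.74 ± 0.61 at 1 h and 7.10 ± 0.56 at 20 h. Its change at 0.5 h (1.69 ± 0.67, adjusted p 0.092) was not called, but it was called by DESeq2 (adjusted p 0.0054) and when only the 6 compared libraries were fitted (0.0025). At 8 h its change was 5.68 ± 0.55, and 4.92 without replicate 1. HSP30, a plasma membrane heat shock protein gene, rose by 2.80 ± 0.67 at 0.5 h. MPC3, a mitochondrial pyruvate carrier gene, fell from 65.9 ± 28 to 4.70 ± 1.17 CPM at 2 h. GSY1 fell by 2.94 ± 0.36 and MAL31 by 2.60 ± 0.26 at 0.5 h. Among the larger falls were, at 8 h, those of the transcription factor gene MGA1 (-2.45 ± 0.35), the leucine synthesis gene LEU1 (-2.29 ± 0.24) and ACO1 (-2.28 ± 0.16). At 20 h they included MAL31, the low-affinity glucose transporter gene HXT1 (-2.21 ± 0.16) and the flavohemoglobin gene YHB1 (-1.99 ± 0.23).

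Heat shock chaperones rose at 0.5 to 4 h and at 20 h, with 9, 9, 11, 9 and 14 of 22 members up, none down, and medians of 0.78, 0.98, 1.15, 0.94 and 1.79. Adjusted over the list alone, 10 and 13 rose at 0.5 and 2 h. The adjusted p was 3.48e-07, 3.82e-08, 9.53e-09, 6.17e-05 and 0.00136, and the adjusted p was 0.528 to 0.789 with an estimated correlation. At 8 h the list was not called (8 up, median 0.57, adjusted p 0.161). The medians of the list at 20 h were 0.10, 1.03 and 2.76 in replicates 1, 2 and 3, and without replicate 3 its adjusted p was 0.0942. At 20 h BTN2, a protein-sorting gene, rose by 4.27 ± 0.67, SSA4 by 6.38 ± 0.67 and HSP26 by 5.76 ± 0.70, which became 2.27, 4.80 and 4.88 without replicate 3. The small heat shock protein gene HSP42 rose by 3.12 ± 0.58, and by 1.57 without it. HSP104, the disaggregase gene, rose by 1.84 ± 0.49 at 2 h and 2.38 ± 0.50 at 20 h, and its 20 h call was lost without replicate 3 (0.94) and when only the 6 compared libraries were fitted (adjusted p 0.0518). The calls of HSP104 at 0.5, 1 and 8 h (1.45, 1.59 and 1.27) were lost when single libraries were left out, with adjusted p up to 0.15, 0.127 and 0.119. HSP26 at 8 h rose by 5.68 ± 0.70, and by 4.71 without replicate 3.

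The general stress list fell at 0.5 h (1 up and 1 down of 19, 2 up when adjusted over the list alone, median -0.54, adjusted p 0.00202). It rose at 8 h (6 up, 1 down, 0.83, 0.0134) and 20 h (10 up, 1.1, 0.000274), and the adjusted p was 0.59, 0.656 and 0.463 with an estimated correlation. In the other EtOH lists, the counts adjusted over the list alone equalled those over all genes. YGP1, a secreted stress glycoprotein gene, rose by 2.30 ± 0.20 at 20 h, and SPI1, a cell wall protein gene, by 3.67 ± 0.48, or 2.37 without replicate 3. The unfolded protein response list rose at 4 h (3 of 14 up, median 0.37, adjusted p 0.00776, and adjusted p = 0.59 with an estimated correlation), and its adjusted p was 0.0868 without replicate 1. KAR2, the Hsp70 gene of the endoplasmic reticulum, rose by 1.47 ± 0.27 and the oxidoreductase gene ERO1 by 1.45 ± 0.28 at 4 h. KAR2 lost its 2 h call (1.09) without replicate 1 (0.82) and its 20 h call (1.17) without replicate 3 (0.66). The proteasome list fell at 2, 4, 8 and 20 h (medians -0.11, -0.24, -0.46 and -0.18, adjusted p 0.0431, 0.000164, 7.49e-08 and 0.0383) with 0 of 32 members down and 1 up at 20 h. The adjusted p was 0.84, 0.656, 0.485 and 0.84 with an estimated correlation. The call ended at 2 h without replicate 1 or 2 (0.14 and 0.067) and at 20 h without replicate 3 (0.816). RPN4, the proteasome regulator gene and the member that rose at 20 h (1.04 ± 0.33), had a change of -0.09 without replicate 3. Autophagy genes fell at 0.5 h (1 of 15 down, median -0.17, adjusted p 0.0221) and rose at 20 h (2 up, 0.70, 0.016), with adjusted p = 0.653 and 0.642 with an estimated correlation. Without replicate 3 these adjusted p were 0.0533 and 0.0547. ATG8 rose by 1.80 ± 0.24 at 20 h.

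Hexose transporter genes fell from 0.5 to 4 h, with 5, 4, 4 and 4 of 7 members down and medians of -1.45, -1.08, -1.05 and -1.23. The adjusted p was 3.82e-08, 3.81e-07, 6.19e-05 and 0.0023. The call held at 0.5 and 1 h (adjusted p = 0.0171 and 0.0229 with an estimated correlation), and at 2 and 4 h the estimate gave an adjusted p of 0.0689 and 0.179. HXT4 fell by 2.10 ± 0.31 at 0.5 h. Sphingolipid genes fell at all 6 times, with 1, 1, 1, 2, 1 and 0 of 18 down, medians of -0.10, -0.10, -0.16, -0.30, -0.47 and -0.48 and adjusted p from 7.7e-05 to 0.0102. The call held at 4 and 8 h (adjusted p = 0.033 at both with an estimated correlation), and elsewhere the estimate gave an adjusted p of 0.0689 to 0.179. SUR1 and IPT1, which act in complex sphingolipid synthesis, fell by 1.35 ± 0.22 and 1.08 ± 0.13 at 4 h. Ergosterol genes fell from 2 to 20 h (0, 1, 5 and 5 of 24 down, medians -0.20, -0.35, -0.67 and -0.60, adjusted p 6.67e-09 to 0.0014, and adjusted p = 0.28 to 0.656 with an estimated correlation). ERG13, the HMG-CoA synthase gene, fell by 1.29 ± 0.13 and ERG25, a sterol demethylation gene, by 1.20 ± 0.13 at 8 h. ERG11 had changes of -0.95 ± 0.09 and -0.92 ± 0.09 at 8 and 20 h (adjusted p 6.6e-10 and 1.1e-09), under the log2 limit, and was not called. Eisosome genes fell from 0.5 to 4 h (0, 1, 2 and 3 of 10 down, medians -0.33, -0.33, -0.39 and -0.56, adjusted p 0.000881 to 0.00232, and adjusted p = 0.306 to 0.376 with an estimated correlation). EIS1 and PUN1 fell by 1.28 ± 0.13 and 1.36 ± 0.15 at 4 h. Cell wall genes fell from 0.5 to 4 h (2, 3, 3 and 3 of 20 down, medians -0.36, -0.48, -0.48 and -0.54, adjusted p 1.03e-06 to 3.65e-05, and adjusted p = 0.142 to 0.201 with an estimated correlation). NCW2 and YPS1 fell by 1.00 and 1.02 at 1 h, and both calls ended in several fits that left out 1 library (changes down to -0.91 and -0.93). SLT2 had changes of -1.0 to -0.44 with adjusted p of 1.8e-06 to 0.0057, short of the log2 limit, and was not called. Multidrug genes fell from 0.5 to 4 h (1, 2, 1 and 1 of 13 down, medians -0.34, -0.40, -0.39 and -0.38, adjusted p 0.000102 to 0.00212, and adjusted p = 0.142 to 0.239 with an estimated correlation). The ABC transporter gene SNQ2 fell by 1.21 ± 0.13 at 8 h, and PDR12 was not called. The fatty acid and phospholipid list was not called (medians -0.01 to 0.18, adjusted p 0.145 to 0.746). INO1 rose by 3.93 ± 0.50 and OPI3 by 3.21 ± 0.25 at 8 h, and OLE1 fell by 1.76 ± 0.29. PMA1 fell by 1.24 ± 0.17 at 8 h.

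Single-copy ribosomal protein genes fell at 8 and 20 h (8 and 16 of 19 down, 1 up, medians -0.93 and -1.34, adjusted p 0.00136 and 3.68e-07, and adjusted p = 0.732 and 0.528 with an estimated correlation). RPL3 fell by 1.57 ± 0.20 and RPS2 by 1.57 ± 0.20 at 20 h. Ribosome biogenesis genes rose at 0.5 and 1 h (medians 0.34 and 0.26, no member called of 26) and fell at 20 h (2 down, -0.44). Their adjusted p was 7.52e-05, 0.000755 and 0.00154 (adjusted p = 0.692, 0.787 and 0.789 with an estimated correlation), and 0.0956 at 20 h without replicate 3. Glycolysis genes fell at 8 and 20 h (3 and 2 of 14 down, 1 up, medians -0.67 and -0.63, adjusted p 0.000481 and 0.00136, and adjusted p = 0.528 and 0.59 with an estimated correlation). PDC1, the main pyruvate decarboxylase gene, fell from 24100 ± 948 to 7830 ± 1690 CPM at 8 h and the pyruvate kinase gene CDC19 by 1.21 ± 0.11, while ENO1 rose by 2.83 ± 0.38. Trehalose and glycogen genes fell from 0.5 to 4 h (4, 3, 4 and 5 of 16 down, 1 up before 4 h, medians -0.59, -0.44, -0.52 and -0.55, adjusted p 1.39e-09 to 0.000445, and adjusted p = 0.179 to 0.59 with an estimated correlation). TPS2 and TPS1, which act in trehalose synthesis, fell by 1.75 ± 0.23 and 1.28 ± 0.13 at 8 h. TCA and glyoxylate genes fell at 0.5, 1 and 2 h (0, 0 and 1 of 21 down, 1 up at each, medians -0.30, -0.26 and -0.28, adjusted p 0.00199, 0.01 and 0.0166, and adjusted p = 0.199 to 0.342 with an estimated correlation). The 2 h adjusted p was 0.0708 without replicate 2. At 8 h, where the list was not called (adjusted p 0.823), the lactate permease gene JEN1 rose by 2.03 ± 0.15 and the isocitrate dehydrogenase genes IDH1 and IDH2 fell by 1.70 ± 0.18 and 1.82 ± 0.14.

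Phosphate genes rose from 0.5 to 4 h (1, 2, 2 and 2 of 10 up, medians 0.49, 0.47, 0.38 and 0.45, adjusted p 2.44e-05 to 0.0244, and adjusted p = 0.239 to 0.655 with an estimated correlation), and the 4 h adjusted p was 0.0547 without replicate 3. PHM8, a nucleotide phosphatase gene, rose by 2.25 ± 0.21 and PHO84 by 1.47 ± 0.20 at 20 h. Iron uptake genes rose at 0.5 h (1 of 17 up, median 0.32, adjusted p 0.0341, and adjusted p = 0.778 with an estimated correlation), and the adjusted p was 0.459 without replicate 3. The haploid mating genes fell at 20 h (6 of 9 down, 1 up, median -1.28, adjusted p 0.000146, and adjusted p = 0.132 with an estimated correlation), and STE2 fell by 1.61 ± 0.10. Not called at any time were the respiratory chain (medians -0.24 to 0.03), glycerol and osmotic (-0.16 to 0.19), oxidative stress (-0.19 to 0.03), amino acid (-0.13 to 0.00), cell cycle (-0.19 to 0.13), histone (-0.45 to -0.05), ESCRT (-0.04 to 0.11) and meiosis lists (0.04 to 0.37). Their lowest adjusted p were 0.114, 0.188, 0.361, 0.371, 0.364, 0.0623, 0.606 and 0.303. Among their members, at 20 h the aminotriazole exporter gene ATR1 rose by 1.99 ± 0.22 and the glutathione peroxidase gene GPX2 fell by 1.70 ± 0.11. At 8 h the arginine synthesis gene ARG4 rose by 1.77 ± 0.19. GPD1, a glycerol phosphate dehydrogenase gene, fell by 1.5 ± 0.26 at 8 h while GPP2 rose by 1.73 ± 0.22. Without 1 replicate, 15 EtOH list tests gained a call (adjusted p 0.0023 to 0.0491): histones at 0.5, 8 and 20 h, the fatty acid list at 1, 2 and 4 h, ergosterol, iron and autophagy at 1 h, ribosome biogenesis and the unfolded protein response at 2 h, ribosomal proteins at 4 h, the eisosome at 8 h and phosphate at 8 and 20 h. In the EtOH course, the median, mean and test differed in sign in 27 list tests, and none of these was called.

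**Figure D3:**
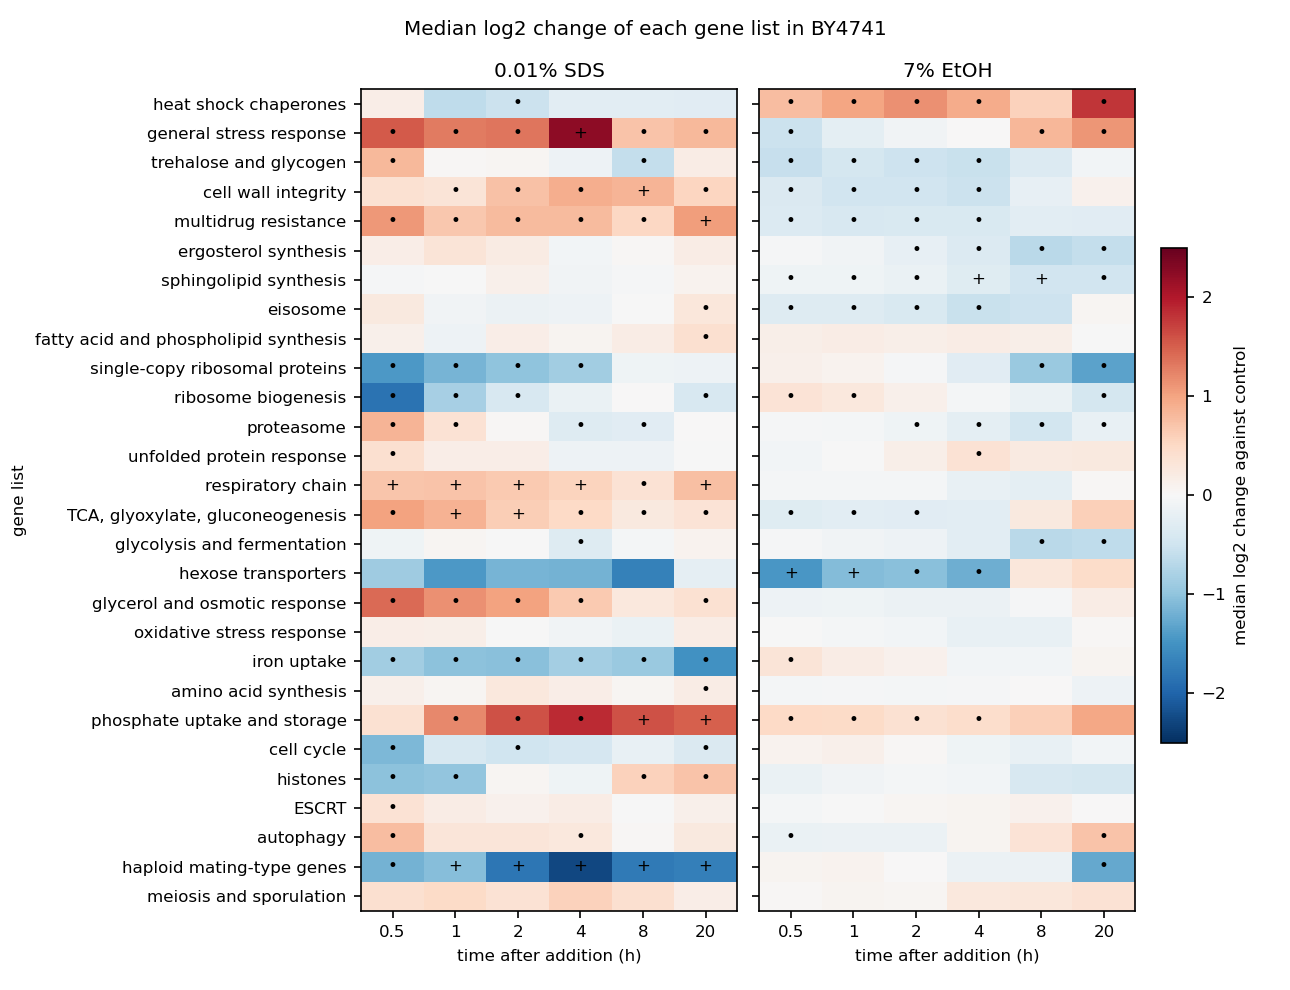
Median log2 change against the control (color) of 28 gene lists (y axis) at each time after addition in hours (x axis) in BY4741, for SDS and EtOH. A dot marks a list called by camera and a plus a call that also held with an estimated correlation: 81 of 168 tests were called for SDS, 17 with a plus, and 61 of 168 for EtOH, 4 with a plus.

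EtOH against SDS in BY4741. The direct comparison asked where the responses to the stresses differed at matched times. SSA4, BTN2 and HSP30 were higher in EtOH by mean log2 differences of 5.0, 3.57 and 3.57 over the 6 times (ranges 4.33 to 6.33, 2.25 to 5.52 and 2.82 to 4.70). TIP1 was higher by 3.10 (1.85 to 3.95), and ATG41, an autophagy gene, by 3.06 (1.74 to 4.09). Higher in SDS were RTA1 (-3.65, -4.64 to -2.38), the cell wall gene NCW2 (-2.96, -4.15 to -1.95), GRE2 (-2.86, -4.15 to -2.03) and ACO1 (-2.74, -3.52 to -2.11). Mean levels over the 6 times were 3310 CPM in EtOH and 107 CPM in SDS for SSA4, and 17.2 and 240 CPM for RTA1. These are means of 18 libraries per stress, with 3 replicates at each of the 6 times, and not of 18 independent cultures. The F test treated all libraries as independent, although 33 of 39 BY4741 libraries correlated best with their own replicate number.

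Of 6101 genes, 2223 (36.4%) differed at 1 time or more, and the adjusted p of the 9 genes named here was 6.5e-11 or lower. At 20 h the differences of SSA4, BTN2, HSP30 and ATG41 (6.33, 5.52, 4.70 and 4.07) became 4.75, 3.51, 2.40 and 1.82 without EtOH replicate 3. The difference of BTN2 at 1 h (3.85) became 4.56 without SDS replicate 1. The heat shock chaperones were higher in EtOH at all 6 times (7, 16, 17, 17, 9 and 15 of 22 higher, medians 0.63, 1.43, 1.72, 1.25, 0.84 and 1.88, adjusted p 9.26e-09 to 0.0465, and adjusted p = 0.356 to 0.756 with an estimated correlation). Adjusted over the list alone, 18 and 10 were higher at 4 and 8 h, and the 0.5 h adjusted p was 0.094 without replicate 2. In the other lists these counts equalled those over all genes. Iron genes were also higher in EtOH at all 6 times (medians 0.93 to 1.52, adjusted p 5.89e-08 to 9.91e-05, and adjusted p = 0.171 to 0.35 with an estimated correlation).

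Lower in EtOH than in SDS at all 6 times were the respiratory chain (medians -0.79 to -0.56, adjusted p = 0.0124 to 0.0225 with an estimated correlation), cell wall (-1.68 to -0.56) and multidrug genes (-1.44 to -1.18). The cell wall call held at 2, 4 and 8 h (adjusted p = 0.0124 to 0.0225 with an estimated correlation; 0.315, 0.14 and 0.232 at 0.5, 1 and 20 h). The multidrug call held at 0.5, 2, 4 and 8 h (0.0124 to 0.0393, and 0.0643 and 0.0854 at 1 and 20 h). TCA genes were lower from 0.5 to 4 h (medians -1.11 to -0.81, adjusted p = 0.0132 to 0.031 with an estimated correlation). The mating genes were higher in EtOH from 0.5 to 8 h (medians 1.39 to 1.84), a call that held from 1 h on (adjusted p = 0.0124 to 0.0225 with an estimated correlation, and 0.0666 at 0.5 h). Sphingolipid genes were lower in EtOH at 2, 8 and 20 h (medians -0.27, -0.50 and -0.60, adjusted p = 0.181, 0.0124 and 0.0124 with an estimated correlation). The remaining calls were lost with an estimated correlation, where the lowest adjusted p of a list was 0.0505. They put general stress genes lower in EtOH from 0.5 to 4 h (medians -2.05, -1.17, -1.47 and -2.21), glycerol genes (-1.41 to -0.70) and autophagy genes (-1.01 to -0.34) lower over the same times, ergosterol genes lower from 1 to 20 h (-0.75 to -0.34), and phosphate genes lower from 2 to 20 h (-0.93 to -0.47). Ribosomal protein genes were higher in EtOH from 0.5 to 4 h (1.56, 1.23, 0.89 and 0.61) and lower at 8 and 20 h (-0.81 and -1.18). Ribosome biogenesis and cell cycle genes were higher from 0.5 to 2 h (2.11, 1.07 and 0.54, and 1.20, 0.63 and 0.47). Histone genes were higher at 0.5 and 1 h (0.74 and 0.84) and lower at 8 and 20 h (-0.98 and -1.19). Trehalose genes were lower from 0.5 to 4 h (-1.31 to -0.40) and higher at 8 h (0.56). Proteasome genes were lower at 0.5, 1 and 20 h (-0.90, -0.41 and -0.20), glycolysis genes at 8 and 20 h (-0.61 and -0.75), and eisosome genes at 2, 4 and 8 h (-0.43, -0.42 and -0.32). ESCRT genes were lower at 0.5 h (-0.31) and the unfolded protein response was higher at 4 h (0.47). Calls that ended without 1 replicate were those of the histones (0.0558) and ESCRT genes (0.0544) at 0.5 h, the cell cycle at 1 h (0.0976), the eisosome at 2 h (0.0559) and 8 h (0.0558 and 0.0683), trehalose (0.0514) and autophagy (0.072) at 4 h and the proteasome at 20 h (0.334). The fatty acid, hexose transporter, oxidative stress, amino acid and meiosis lists were not called (lowest adjusted p 0.291, 0.131, 0.0619, 0.113 and 0.286). Without 1 replicate, 15 tests gained a call (adjusted p 0.00457 to 0.0492): oxidative stress at 0.5 h, the proteasome at 2 and 8 h, sphingolipids and amino acids at 4 h, ribosome biogenesis at 4, 8 and 20 h, the unfolded protein response and TCA genes at 8 h, autophagy at 8 and 20 h and the general stress, cell cycle and ESCRT lists at 20 h. The median, mean and test differed in sign in 14 tests, none of them called.

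SDS and EtOH in *S. pastorianus*. The same comparisons were made for the lager yeast, whose genes carry only identifiers in the sources used here. After 2 h of SDS, SCPA_0S00910 rose from 6.27 ± 0.48 to 511 ± 57.8 CPM (SD, n = 3), a log2 change of 6.35 ± 0.49 (SE), and SCPA_0H00740 fell from 216 ± 75.1 to 12.7 ± 3.42 CPM, a change of -4.10 ± 0.53. After 2 h of EtOH, SCPA_0F01520 rose from 3.68 ± 0.464 to 4560 ± 738 CPM, a change of 10.27 ± 0.81, and SCPA_0W01440 fell from 645 ± 172 to 37.3 ± 12.2 CPM, a change of -4.11 ± 0.29. The annotation gives no name or function for these 4 genes, which lie on scaffolds without chromosome names.

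SDS called 1405, 1609, 1638, 1066, 495 and 481 of 10688 genes from 0.5 h to 20 h in turn, of which 679, 833, 1004, 880, 301 and 345 rose. EtOH called 841, 1437, 2292, 1641, 1114 and 880 genes, of which 600, 910, 1249, 1118, 873 and 611 rose. At any time 2519 genes (23.6%) changed in SDS and 3224 (30.2%) in EtOH, where 1596 changed most at 2 h. The stresses differed in 2978 genes (27.9%). Replicates differed in the size of their change relative to the mean of the others over the called genes. Replicates 1, 2 and 3 lay at 1.21, 0.87 and 0.82 at SDS 20 h. They lay at 0.88, 0.95 and 1.17 at EtOH 0.5 h and at 0.87, 0.96 and 1.16 at EtOH 1 h. The mean SD of log2 CPM between replicates was 0.082 to 0.170 over the *S. pastorianus* groups. At 2 h of EtOH 21.4% of tested *S. pastorianus* genes were called against 2.84% of BY4741 genes, and at 20 h the shares were 8.23% and 13.9%. The difference between the yeasts was not tested gene by gene.

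**Figure D4:**
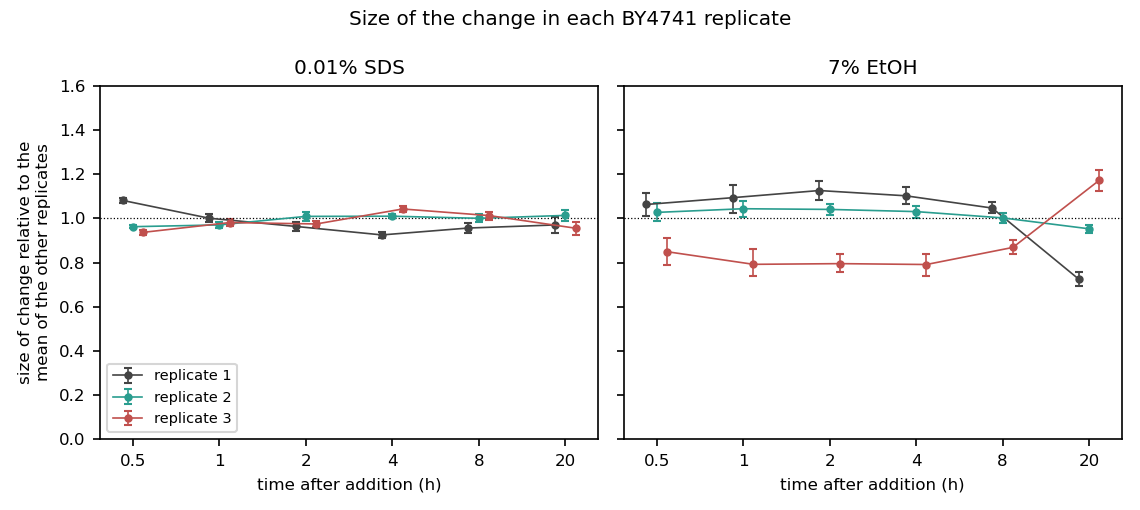
Size of the change against control in each BY4741 replicate, relative to the mean of the other replicates (y axis, a ratio where 1 is equal), by time after addition in hours (x axis), for SDS and EtOH. Points are slopes over the called genes and bars are 95% bootstrap intervals drawn over these genes, not over cultures. EtOH replicate 3 lay at 0.79 to 0.87 from 0.5 to 8 h and at 1.17 at 20 h, and replicate 1 at 0.725 at 20 h.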

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

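The direct comparison of EtOH with SDS marked gene lists that were called in opposite directions under the 2 stresses and differed in the test of EtOH against SDS itself. In the part below, the test of a weaker EtOH effect in replicate 3 was chosen only after its result was seen.

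At 0.5 h, median log2 differences of EtOH minus SDS were -2.05 for general stress genes (19 members), -1.31 for trehalose and glycogen, -1.44 for multidrug resistance, 2.11 for ribosome biogenesis, -1.11 for the TCA and glyoxylate list, 1.09 for iron uptake and -1.01 for autophagy. At 1 h they were -0.83 for cell wall integrity, -1.31 for multidrug resistance, 1.07 for ribosome biogenesis and -0.91 for the TCA list. At 2 h they were 1.72 for heat shock chaperones, -1.27 for cell wall integrity, -1.28 for multidrug resistance and -0.81 for the TCA list, and at 4 h -1.68 for cell wall integrity and -1.42 for multidrug resistance. The adjusted p of these differences ran from 2.74e-14 to 0.000176. The lists were marked by this same test, so these values are not further support. With an estimated correlation the TCA differences, multidrug resistance at 0.5, 2 and 4 h and cell wall integrity at 2 and 4 h still passed, and the others did not. The opposite calls themselves are lost with it: none of the EtOH calls of these lists passed (adjusted p 0.142 to 0.787), and of the SDS calls only the TCA list at 1 and 2 h did (0.0355 and 0.0431).

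Other groupings of the same libraries were refitted for each count of genes, with only the libraries of that test in the fit, so that the real counts here differ from those reported with all 39 libraries. For each comparison of 1 time with the control, 10 splits of the 6 libraries exist, so the share of splits with as many genes cannot be under 0.1. In all 24 such comparisons 1 of 10 splits, the real one, reached the real count, which lay between 149 and 2296 genes, and the highest other split gave 0. Every other split puts treated and control libraries in both arms, so a treatment effect adds to the spread within arms and holds calls down. The 0 therefore does not measure false calls. For the tests over all times, 1 of 100 groupings, the real one, reached the real count. This share covers only a random grouping of freely exchanged libraries. These groupings did not keep replicate numbers together, although 33 of 39 BY4741 and 28 of 39 *S. pastorianus* libraries correlated best with their own number, so they do not represent repeated samples of 1 culture. In BY4741 the real and highest other counts were 1551 and 431 for SDS, 1045 and 429 for EtOH and 2223 and 1703 for the difference between the stresses. In *S. pastorianus* they were 2510 and 1140, 3222 and 1270, and 2981 and 2129. For the difference between the stresses, labels were exchanged within each time, so a grouping could keep or reverse the real split at some times. That alone can give high counts.

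After 2 h of EtOH a larger share of genes was called in *S. pastorianus* than in BY4741. With the *S. pastorianus* libraries thinned to the BY4741 totals, the called share was 21.5% against 2.84%, a ratio of 7.57, which argues against deeper sequencing. Genes changed at least 2-fold, counted without any p, made up 21.5% and 3.82%, a ratio of 5.62, which argues against a smaller spread between replicates. Without thinning, the ratio of the called shares was 3.06 to 7.56 from 0.5 to 4 h of EtOH, 1.02 at 8 h and 0.592 at 20 h. In SDS it ran from 0.69 to 1.62, so the larger share was limited to the earlier EtOH times. Genes could not be matched between the yeasts, so the shares are not over the same genes. A difference between the yeasts in their response to EtOH at these times may remain, and other differences between the cultures of the yeasts were not tested.

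In BY4741, replicate 3 of the EtOH course changed less than replicates 1 and 2 from 0.5 to 8 h over the called genes of each time, with SSA4 at 2140 CPM at 2 h against 6590 and 4650, but not in the heat shock chaperones at 8 h, where their median was 0.96 against 0.66 and 0.29 and SSA4 lay at 4140 CPM against 2530 and 1450. A weaker effect of EtOH in that culture at every time is argued against by the size of its change at 20 h. This was 1.17 times that of the others, with SSA4 at 9690 CPM against 608 and 2180 CPM. Replicate 1 was low at 20 h (0.725), which adds to this ratio. The genes were called in a fit that included replicate 3, which can also raise the ratio. Its 95% interval of 1.13 to 1.22 was drawn over the called genes and does not measure spread between cultures. The heat shock chaperones, a list written beforehand, had a median of 2.76 in replicate 3 at 20 h, against 0.10 and 1.03 in replicates 1 and 2. Of the 720 orders of the 6 replicate 3 libraries, 0 lay closer to replicates 1 and 2 than the labelled order, which argues against times exchanged within replicate 3. Depth differed most at 8 h, with totals of 6216014, 21167236 and 3105804 counts in replicates 1, 2 and 3. The relative size of replicate 3 at 8 h was 0.869, and 0.868 after thinning to equal totals, which argues against depth at that time. From 0.5 to 4 h its totals were 7342423 to 8979393 counts, against 6838994 to 9125669 in replicates 1 and 2. Thinning could therefore change little at those times, where the highest relative size after it was 0.831. Libraries exchanged between groups cannot be told apart from a slow change between neighboring times, since 11 of the 18 EtOH libraries lay nearer another EtOH time than their own, and a slower course in that culture may be a candidate explanation that was not tested.

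After 8 h of EtOH, low-level genes rose and high-level genes fell in BY4741, with a Spearman correlation of -0.57 between change and control level, against -0.43 at SDS 4 h, -0.41 at EtOH 4 h, -0.47 at EtOH 20 h and -0.50 to -0.17 over the times and stresses in *S. pastorianus*, so the pattern is not particular to this group. The median log2 change was 0.40 for 796 genes of 5 to 20 CPM and -0.68 for 365 genes over 500 CPM. With the level taken from SDS libraries of 8 h the correlation was -0.487, which argues against noise of the shared controls as the whole cause, and given gene length it was -0.563, which argues against length. A background added to every gene cannot be told apart, since the 19.5% of the 796 genes that were lower at 8 h pass the 10% set beforehand but are the lowest share of the 12 BY4741 comparisons, and genes can fall above a background. A shift of RNA from abundant to rare transcripts may remain, and time in culture, which the design does not separate from EtOH, stays open.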

How the results depend on the processing

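The counts of called genes were recomputed with DESeq2, RLE size factors, no low-count filter, a replicate block, fits of the 6 compared libraries and with each library left out, and all stayed within 1.5 times the reported count. In BY4741 the block gave 1535 genes for SDS, 1097 for EtOH and 2220 for their difference. Chosen after seeing the data, the tests over all times without 20 h gave 714 genes for EtOH in BY4741 against 1107, since the comparison with most called genes was left out, and 1501 and 1975 for SDS and the difference. Camera with an estimated correlation called 17, 4 and 23 lists for SDS, EtOH and their difference in place of 81, 61 and 94. How far the estimate widens the null distribution depends on how much the members of a list vary together between replicates. The calls lost with it therefore rest on the preset correlation. Fry called 108, 81 and 135, of which 79, 57 and 94 were shared. The block shared 81, 61 and 93 list calls and RLE 81, 61 and 94. With the block, the heat shock chaperones lost their call for EtOH against SDS at 0.5 h (adjusted p 0.0517). EtOH calls gained with the block were ribosome biogenesis at 2 h (0.0416), the eisosome at 8 h (0.0369) and phosphate at 8 and 20 h (0.0416 and 0.0274). List tests without 1 replicate, also chosen after seeing the data, shared 77 to 80, 54 to 59 and 89 to 93, and 11, 15 and 15 list tests gained a call in at least 1 of them. Among 467 results for named genes 325 were called, of which 30 lost the call under at least 1 alternative and 1 reversed: RPN4 at EtOH 20 h was 1.04, and -0.094 without EtOH replicate 3. The cause was not tested. Of the 142 not called, 12 gained the call under at least 1 alternative, among them HSP12 at EtOH 0.5 h, HSP26 at SDS 20 h, SLT2 at EtOH 2 h, KAR2 at EtOH 8 h and OLE1 at EtOH 20 h (-0.62, and -1.54 without EtOH replicate 1). The largest range on leaving out a library was 689 to 1053 for BY4741 EtOH at 20 h. Orthologue and homeologue results with their alternatives were not run, since the yeasts' genes could not be matched. Depth limits BY4741 more than *S. pastorianus*, and a count of 0 allows 0.966 CPM in the smallest BY4741 library.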

Other observations

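Families of genes that share the letters of their symbol were tested in BY4741, which was chosen after the data were seen and covers 1224 tests per stress. After 0.5 h of SDS, 6 of 11 ADE genes, which act in purine synthesis, fell (median log2 change -1.27, adjusted p 0.00364), as did 5 of 7 RPA genes (-1.98, adjusted p 0.000522) and 13 of 18 UTP genes (-1.30, adjusted p 1.19e-06), which act in making ribosomal RNA. At 1 h of SDS, 5 of 9 SDH genes rose (1.05, adjusted p 0.000129), and at 2 h 3 of 11 MCM genes fell (-0.61, adjusted p 0.00029). None of these 5 passed with an estimated correlation (adjusted p 0.686, 0.581, 0.64, 0.437 and 0.312). The families are groups of symbols and hold genes of more than 1 function.

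The 3 tests below were chosen only after their results were seen. The a-specific mating genes fell in SDS, at 4 h STE2 by 2.27 ± 0.10, MFA2 by 2.69 ± 0.16 and BAR1 by 2.32 ± 0.14. An a/alpha diploid would repress haploid-specific genes, and alpha cells would keep these and bring alpha-specific transcripts. Of 8 haploid-specific genes at 4 h, RME1 rose by 1.16 ± 0.15 and GPA1 fell by 1.35 ± 0.09. NEJ1 and STE5 had changes of 0.29 ± 0.14 and -0.01 ± 0.09, and STE4, STE18, FUS3 and FAR1 of -0.62 ± 0.09, -0.52 ± 0.19, -0.85 ± 0.12 and -0.83 ± 0.11, which were not called. In edgeR GPA1, STE4, STE18, FUS3 and FAR1 fell with adjusted p of 1.5e-13 to 0.023, while RME1, NEJ1 and STE5 did not fall. Not all haploid-specific genes fell, which argues against a/alpha diploids as the whole source. RME1, NEJ1 and STE5 were taken as the deciding genes after their values were seen. At its fitted log2 change of -2.27, the fall of STE2 alone would need about 79.3% alpha cells. The alpha-specific gene SAG1 (40.9 CPM in the control) had a change of 0.17 ± 0.08, and SST2, FUS1 and AGA1, which both haploid cell types express, fell by 2.21 ± 0.13, 2.2 ± 0.22 and 1.78 ± 0.15, which argues against alpha cells as the whole source. Of the alpha-specific genes at lower levels, STE3, the a-factor receptor gene, rose by 2.04 ± 0.36 from 1.32 CPM, and AFB1 and MF(ALPHA)2 had changes of 0.5 ± 0.20 and 0.77 ± 0.18, which were not called. STE3 also rose by 2.79 ± 0.34 at 8 h of EtOH, where STE2 fell by 1.3 ± 0.10 and MFA1 and MFA2 had changes of 0.32 ± 0.20 and 0.07 ± 0.14. At 20 h of EtOH MFA1, MFA2, BAR1 and STE2 had changes of -1.75 ± 0.21, -1.19 ± 0.15, -1.54 ± 0.13 and -1.61 ± 0.10, all called. AGA2 was not called there (-0.99 ± 0.18), and STE3 rose by 2.52 ± 0.35. The fall of a-specific genes was therefore not particular to SDS. A smaller share of alpha cells is not excluded. No biological explanation was tested.

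Genes within 20 kb of a chromosome end rose after 8 h of EtOH, with a median log2 change of 0.30 for 202 genes against -0.01 elsewhere. The central 95% of 10000 sets of genes from elsewhere with matched control levels had medians of 0.26 to 0.46. The lower level of genes near chromosome ends, a median of 8.03 CPM against 65.6 CPM, is a candidate explanation for the rise. In 44.6% of the 202 genes, over 20% of the 50-base sequences occur more than once in the genome, and the others had a median of 0.25. The handling of reads that map to several genes is not given in the sources used here.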
